A study of Caulobacter sp. Root343 and Escherichia coli with 12 samples.

How the data were processed

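Total RNA was sequenced from Caulobacter sp. Root343 at 3 growth phases (mid log, late log and early stationary, 3 libraries each) and from E. coli MG1655 carrying a Bil system on the plasmid pJH119 (3 libraries). The groups and replicate numbers come from the labels. Nothing in the labels says that the libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Per the labels' protocols, an amount of cells corresponding to an OD600 of 2 was taken at each phase and stopped with ethanol and phenol, RNA was taken up in TRIzol and treated with DNase I, rRNA was depleted with RiboCop META, and libraries were made by ligating an adapter to the 3' end of fragmented RNA and read with 100 single-end cycles on a NextSeq instrument. E. coli was induced with anhydrotetracycline (aTc) at 25 ng per ml and taken at mid log. Trim Galore 0.6.7 and featureCounts 2.0.3 are named in the submitters' processing notes. The aligner, the strand setting of the counting and the handling of reads that fall in overlapping genes are not given in the sources used here.

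The values were deposited as TPM (transcripts per 1 M) per feature and library, in 1 table per Caulobacter phase and 1 for E. coli. The mid log and late log tables list 4883 features each and 4713 are listed for early stationary. The 170 features outside the early stationary table were low: their highest TPM was 5.15 and the median mid log TPM was 0.326. A listed feature had at least 30 reads summed over the 3 early stationary libraries. Features were used by the symbol or locus tag in the tables. In Caulobacter 757 features carry a symbol and 4126 carry a locus tag only, and the tables hold no product names. Coordinates are those of the tables, on the 12 contigs of the Caulobacter assembly and on the MG1655 chromosome and pJH119. The tables' Chr, Start and End columns gave 25 entries that sum several loci. Feature lengths were multiples of 3 for 99.0% of features, so they are coding lengths.

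TPM multiplied by length came out as whole multiples of 1 step per library for 100% of values, within 0.001 of a read, which gives the reads assigned to features. The recovered totals were 11.5 to 13.3 M reads in mid log, 11.9 to 14.3 M in late log, 9.83 to 12.7 M in early stationary and 9.37 to 11.1 M in E. coli. A single read of a 1 kb feature was worth 0.0362 to 0.0494 TPM in Caulobacter, so 3 reads corresponded to 0.109 to 0.148 TPM. These floors cover counting error only. TPM is not a count, so no count model was the main test.

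Caulobacter phases were compared with limma 3.58.1 in R 4.3.3 on log2(TPM + 1) with a mean-variance trend, all 9 libraries in 1 fit and no block. Features with TPM of at least 1 in at least 3 libraries were tested (4609, of which 4535 were taken as protein-coding). Protein-coding here means a length that is a multiple of 3 and at least 96 nt, and not a stable RNA known by its symbol. A stable RNA without a symbol may remain among them. Changes are on the log2(TPM + 1) scale, which understates those of low features. P-values were adjusted by Benjamini-Hochberg and called at 0.05. A second set of values, called scaled here, comes from the same fit after dividing TPM by median-of-ratios size factors (0.794 to 1.17). Median-of-ratios scaling was planned as an alternative before the data were examined. Leading with scaled values was chosen after seeing that the median of all features moved by more than 0.1.

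Gene lists were fixed before the data were examined: 44 lists matched on symbols, of which 17 had at least 5 tested members, 16 had 1 to 4 and 11 had none. The 17 lists were tested with limma's camera with a preset correlation of 0.01, with an estimated correlation and with fry. Members are also counted after adjustment over the list alone. The Bil genes were tested across phases by an exact permutation of the F statistic and their shares by an exact permutation of the difference of means, in SciPy and NumPy. Levels and percentiles have no test.

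Genes are named by this rule: the Bil genes, and in each comparison up to 12 rises and 12 falls with the largest fitted change among features with adjusted p under 0.05, a mean of at least 20 TPM in the higher phase, no overlap between the libraries of the phases, and a gene symbol. The rule was written for product names, which the tables do not give, so the symbol stands in for them. At most 2 risen and 2 fallen locus tags are printed, and of the risen ones those from separate contigs were chosen after their values were seen. From E. coli the Bil genes, the list of plasmid elements and the 15 protein-coding genes with the highest mean TPM are named. Any other gene was chosen after its values were seen, and this is stated where it is named.

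The alternatives were other pseudocounts (0.1 and 5), no filter or TPM of at least 10, coding features rescaled to their own total, median-of-ratios scaling, quantile normalization, only the phases compared, a replicate block, a fold threshold, and leaving out each library in turn. Added after seeing the data were limma's voom on the recovered reads and further settings on the scaled values. The fit and camera were tested on simulated reads for 4601 features with 200 changed. For early stationary against mid log, 88% of features changed by 1.5-fold and 99% of those changed by 2-fold were recovered, with 9 false calls. For early stationary against late log these were 92%, 97% and 10, and 0 false calls were made in the unchanged comparison of late log with mid log. Of 29 unchanged lists 0 were called, and the shifted list was. The simulation gave all features 1 dispersion (0.00357), with no common shift and no outlying library. Its rates may therefore not hold for the real libraries. The unchanged lists were random features simulated independently, so they do not test the preset correlation for genes that vary together. The other software was Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.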

Results

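The series profiled total RNA of Caulobacter sp. Root343, which carries a Bil system, at mid log, late log and early stationary phase. It also profiled E. coli MG1655 that expressed a Bil system from a plasmid. Bil is an antiphage system of 4 genes: bilA encodes a ubiquitin-like protein, bilB an E2-like enzyme, bilC a deubiquitinase-like peptidase and bilD an E1-like enzyme. Each group had 3 libraries. Recovered reads per library ranged from 9.83 to 14.3 M in Caulobacter and from 9.37 to 11.1 M in E. coli. Most of the Caulobacter signal came from stable RNA. The 5S rRNA feature rrf took 44.2% ± 1.33 of TPM in mid log, 40.7% ± 1.79 in late log and 40.2% ± 0.81 in early stationary (SD, n = 3). Protein-coding features took 13.2% ± 0.83, 15.98% ± 1.58 and 17.1% ± 0.44 of TPM. The median feature was also higher in the later phases on the log2(TPM + 1) scale. It was higher by 0.22 in late log and 0.33 in early stationary against mid log, and by 0.11 in early stationary against late log. Changes below are given relative to this shift, as scaled values, with the unscaled counts beside them. Libraries of a group correlated at 0.986 to 0.994 (Pearson r of log2 values across features, which are not independent replicates). Libraries of different phases correlated at 0.984 to 0.993, nearly the same range. Early stationary replicate 3 was the farthest from its group, with r of 0.986 and 0.989 against the other libraries of its phase. Those libraries correlated more closely with every late log library (0.991 to 0.993) than with replicate 3.

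The first question was whether the Bil operon of Caulobacter sp. Root343 depends on growth phase. The Bil genes lie on the minus strand of contig 10, with bilA at 106432 to 106953, bilB at 105933 to 106439, bilC at 105461 to 105985 and bilD at 104109 to 105464. bilA and bilB overlap by 8 nt, bilB and bilC by 53 nt and bilC and bilD by 4 nt, and how reads in overlaps were counted is not given in the sources used here. bilA was the highest of the 4 at 16.1 ± 0.83 TPM in mid log, 19.0 ± 0.73 in late log and 21.9 ± 1.20 in early stationary (SD, n = 3). bilB measured 3.94 ± 0.73, 5.39 ± 0.85 and 5.74 ± 1.24 TPM, bilC 3.33 ± 0.51, 4.47 ± 1.10 and 4.89 ± 0.85 TPM, and bilD 3.28 ± 0.25, 3.83 ± 0.25 and 4.25 ± 0.29 TPM in the same order. The operon sum was 26.6 ± 2.08, 32.6 ± 2.49 and 36.7 ± 3.15 TPM. These values rested on 186 to 275 reads per library for bilA, 36 to 89 for bilB, 34 to 83 for bilC and 94 to 149 for bilD.

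**Figure D1:**
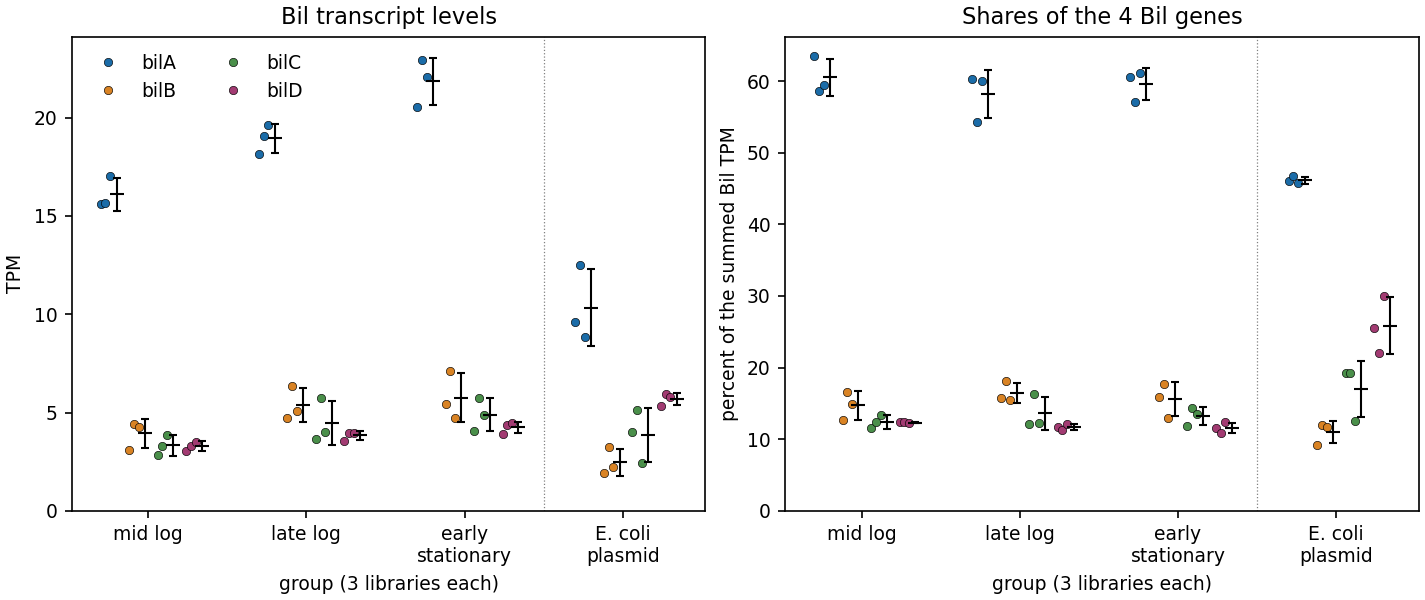
Left, TPM of bilA, bilB, bilC and bilD in each library of the 3 Caulobacter phases and of E. coli carrying the plasmid; right, each gene's percent of the summed Bil TPM. Points are libraries and the bars beside them are mean ± SD of 3. bilD took 11.6 to 12.3% of the Bil TPM in the Caulobacter phases and 25.9% in E. coli.

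Across phases the unscaled levels of bilA, bilD and the sum differed (exact permutation test of the F statistic, 280 distinct arrangements, Benjamini-Hochberg adjusted over 5 values, p = 0.0179 for bilA and the sum and 0.0298 for bilD), and those of bilB and bilC did not pass (p = 0.104 for each). In limma's fit, bilA was 0.42 ± 0.12 higher (log2, SE) in early stationary than in mid log (adjusted p = 0.0169), bilB 0.44 ± 0.16 (0.0408), bilC 0.44 ± 0.16 (0.0412) and bilD 0.30 ± 0.13 (0.0742). These changes were about the size of the shift of all features. After scaling bilA differed by 0.06 ± 0.09 between early stationary and mid log, bilB by 0.14 ± 0.14, bilC by 0.14 ± 0.13 and bilD by -0.00156 ± 0.0948, and the adjusted permutation p-values were 0.835 for bilA, bilB, bilC and the sum and 0.921 for bilD. So no difference in Bil level beyond the common shift passed the test. Unscaled, bilC passed with the replicate block (exact permutation test, adjusted p = 0.0347). That test has 36 distinct arrangements, and bilA, bilC, bilD and the sum all reached its smallest unadjusted p, 0.0278. It was not run on scaled values, so the pass of bilC is not separated from the common shift. With a library left out, the unscaled sum passed for all but mid log replicate 1 (p = 0.0714) and early stationary replicate 2 (0.0536), and bilD did not pass without mid log replicate 1 (0.0893), mid log replicate 2 (0.0655), early stationary replicate 2 (0.0714) or replicate 3 (0.0714), all adjusted p-values of the exact permutation test.

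In Caulobacter the operon stood at intermediate to low ranks. Among 4639 protein-coding features bilA was at percentile 67.3 ± 1.75 in mid log, 66.6 ± 3.04 in late log and 68.3 ± 1.81 in early stationary (SD, n = 3). bilB lay at 27.5 ± 2.77, 30.4 ± 1.296 and 29.5 ± 5.36. bilC was at 23.5 ± 1.65, 25.9 ± 2.95 and 25.8 ± 4.02, and bilD at 23.4 ± 0.51, 22.7 ± 2.23 and 22.9 ± 1.45. In E. coli bilA was at percentile 60.5 ± 3.47, bilB at 34.5 ± 3.31, bilC at 41.1 ± 6.29 and bilD at 48.7 ± 0.53 among 4207 protein-coding features.

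The proportions of the 4 transcripts within a library can be set across organisms. The genes compared are not identical, since their annotated lengths differ. On the plasmid bilA has 492 nt against 522 in Caulobacter, bilB 486 against 507, bilC 522 against 525 and bilD 1386 against 1356. bilA took 60.5% ± 2.60, 58.2% ± 3.40 and 59.6% ± 2.19 of the Bil TPM in the 3 phases and 46.2% ± 0.48 in E. coli (SD, n = 3). bilB took 14.7% ± 2.01, 16.4% ± 1.43 and 15.6% ± 2.39 against 10.96% ± 1.56. bilC took 12.4% ± 0.96, 13.6% ± 2.34 and 13.3% ± 1.23 against 17.0% ± 3.86. bilD took 12.3% ± 0.05, 11.8% ± 0.42 and 11.6% ± 0.73 against 25.9% ± 3.99. Over 9 Caulobacter and 3 E. coli libraries the exact two-sided permutation test of the difference gave adjusted p = 0.00606 for bilA, bilB and bilD, for which all libraries of the organisms were separate, and 0.0227 for bilC. The 9 libraries span 3 phases and are not replicates of 1 group, and per phase the smallest p that 3 against 3 allow is 0.1, the value found for bilA, bilB and bilD in each phase. The bilC difference did not pass without E. coli replicate 1 (Caulobacter minus E. coli -2.79 percentage points, exact adjusted p = 0.0909) or replicate 2 (-2.82, 0.0909), and turned under a log2 ratio to the median Bil gene (Caulobacter minus E. coli 0.22, p = 0.0955).

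Late log was compared with mid log to find features that change before growth stops. By the rule, 10 genes with a symbol rose unscaled (limma, adjusted p from 0.0262 to 0.0471). coaE, the last enzyme of coenzyme A synthesis, was 0.94 ± 0.28 higher on the scaled log2 scale (SE), hemF, coproporphyrinogen oxidase, 0.87 ± 0.29, hemA, the first enzyme of heme synthesis, 0.68 ± 0.15, and ccmC, which delivers heme for cytochrome c maturation, 0.63 ± 0.19. mce, methylmalonyl-CoA epimerase, and cyoE, heme O synthase, were each 0.59 higher. hemH (ferrochelatase, 0.39), lpxC (lipid A synthesis, 0.33), hutI (histidine degradation, 0.29) and ftsW (septal wall synthesis, 0.26) followed. In TPM, hemF stood at 29.2 ± 2.97 in mid log and 71.3 ± 41.8 in late log, hemA at 250.8 ± 31.8 and 490.6 ± 145 and coaE at 11.7 ± 4.69 and 27.0 ± 6.58 (SD, n = 3). None passed after scaling (limma, adjusted p from 0.228 for lpxC and cyoE to 0.352 for mce). Of the 55 features without a symbol that met the rest of the rule, some changed more than coaE, up to 1.86 on the scaled values (99.3 ± 4.93 to 477 ± 275 TPM), and none passed after scaling either (lowest adjusted p = 0.0591 among the 12 largest).

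**Figure D2:**
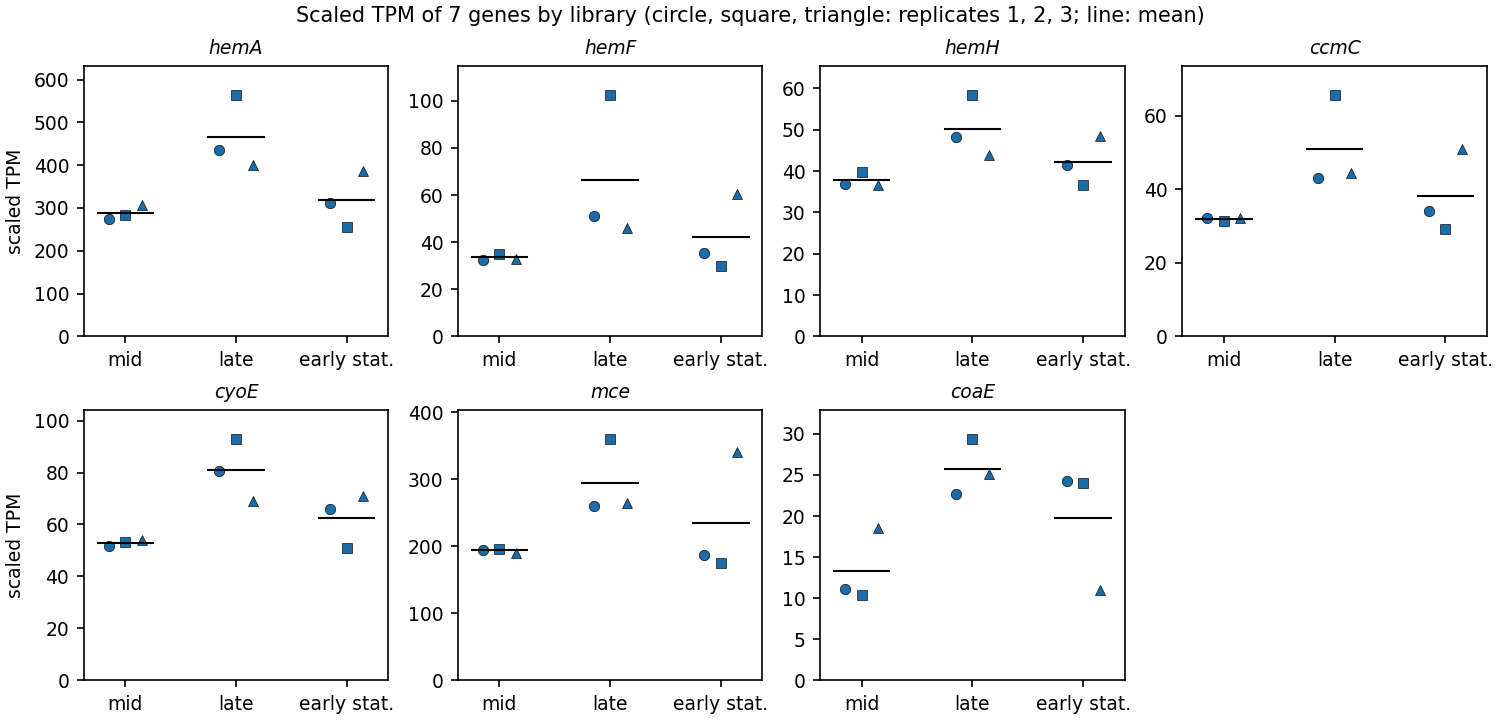
Scaled TPM of hemA, hemF, hemH, ccmC, cyoE, mce and coaE in each Caulobacter library, with replicates 1, 2 and 3 as circles, squares and triangles and the mean as a line. hemF reached 102 in late log replicate 2 and 60.7 in early stationary replicate 3, and lay between 29.9 and 51.1 in the other libraries.

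Unscaled, 118 of 4609 features rose in late log and 0 fell (limma; 1359 had an unadjusted p under 0.05), and after scaling 0 passed (510 unadjusted). Scaled counts were 7 without early stationary replicate 3, 2 without late log replicate 3 and 5 with only the 2 phases compared. The unscaled count was 166 by voom, 63 with a pseudocount of 5 and 471 with only the 2 phases compared. Left-out libraries moved it: it was 1 without mid log replicate 1, 3 without mid log replicate 2, 51 without late log replicate 1, 1 without late log replicate 2, 32 without late log replicate 3 and 437 without early stationary replicate 3.

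**Figure D3:**
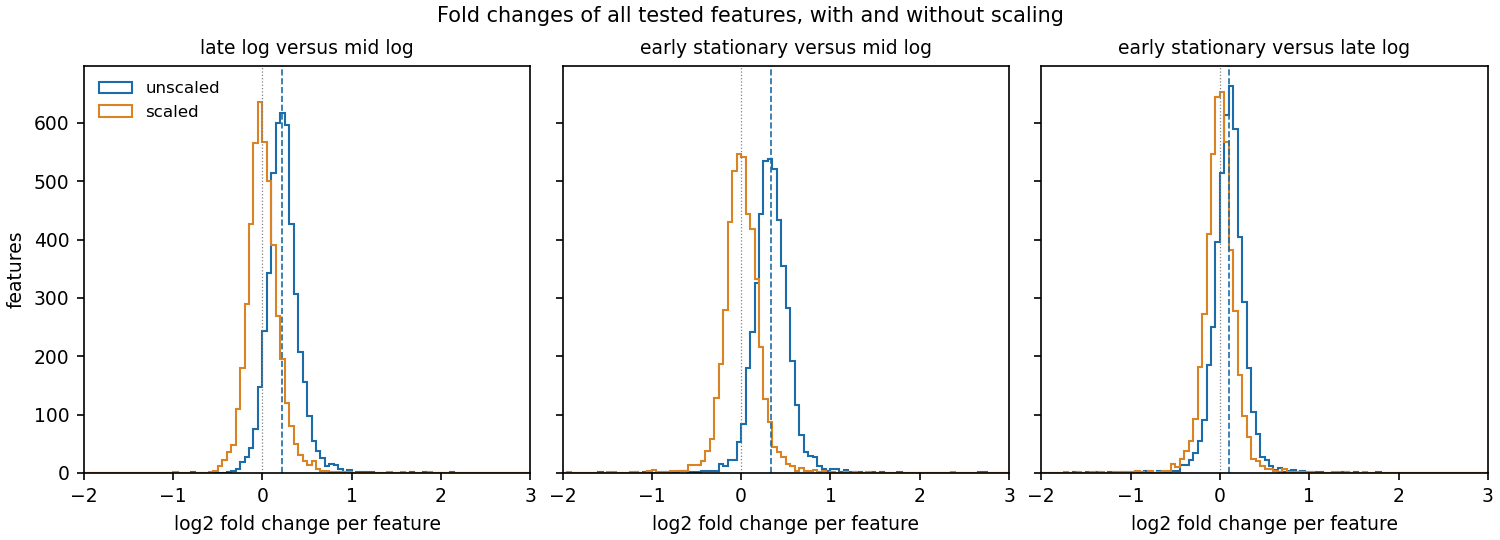
Distribution of log2 fold changes of 4609 tested features for the 3 comparisons, unscaled and after median-of-ratios scaling, with a dashed line at the unscaled median. The unscaled medians are 0.22, 0.33 and 0.11 and the scaled ones lie near 0.

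Early stationary was compared with mid log to find what changes as growth stops. Genes of a 21266 nt stretch at the start of contig 1 fell together. The stretch runs from uraH to the last nearby feature called lower against mid log after scaling, which ends at position 30303. It holds 18 tested features, of which 14 fell against mid log and 14 against late log, with and without scaling. Since such calls set its bounds, these counts describe the stretch and do not test it. Against late log these were the same features with and without scaling, and against mid log 1 differed. uraH, which encodes 5-hydroxyisourate hydrolase of the urate pathway, fell from 32.6 ± 2.17 TPM in mid log to 20.4 ± 3.02 in early stationary (SD, n = 3; scaled log2 change -1.02 ± 0.12, limma adjusted p = 0.00102). The neighbours were chosen after their values were seen: xdhA, xdhB and xdhC (xanthine dehydrogenase, scaled -1.01, -1.22 and -0.93), guaD (guanine deaminase, -0.97), uraD (OHCU decarboxylase, -1.01) and puuE (allantoinase, -0.96) fell. hpxZ in the stretch was at -0.96 and did not pass against mid log after scaling (limma, adjusted p = 0.0865), but fell unscaled (-0.65, 0.0371), whereas 1 unnamed feature fell only after scaling. queF, which makes the queuosine precursor, fell by 0.77 (SE 0.09) at 142 ± 6.16 TPM in mid log and 108 ± 12.4 in early stationary. ASC70_RS00090, an unnamed feature of the stretch, fell by 1.95 ± 0.13. Among the rises, the unnamed ASC70_RS10020 on contig 6 (537094 to 539526) went from 8.79 ± 0.88 to 64.5 ± 4.34 TPM (scaled 2.39 ± 0.22, adjusted p = 0.000232) and ASC70_RS24095 on contig 12 from 62.2 ± 4.52 to 221 ± 50.3 TPM (1.42 ± 0.14, 0.000428). By size of change these were the 1st and 3rd of the risen locus tags that met the rest of the rule; the 2nd, the next feature on contig 6, rose by 2.35 and is not printed by its tag. putA, proline dehydrogenase, and gltB, glutamate synthase, rose by 0.71 ± 0.13 and 0.61 ± 0.11 and were chosen after their values were seen.

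**Figure D4:**
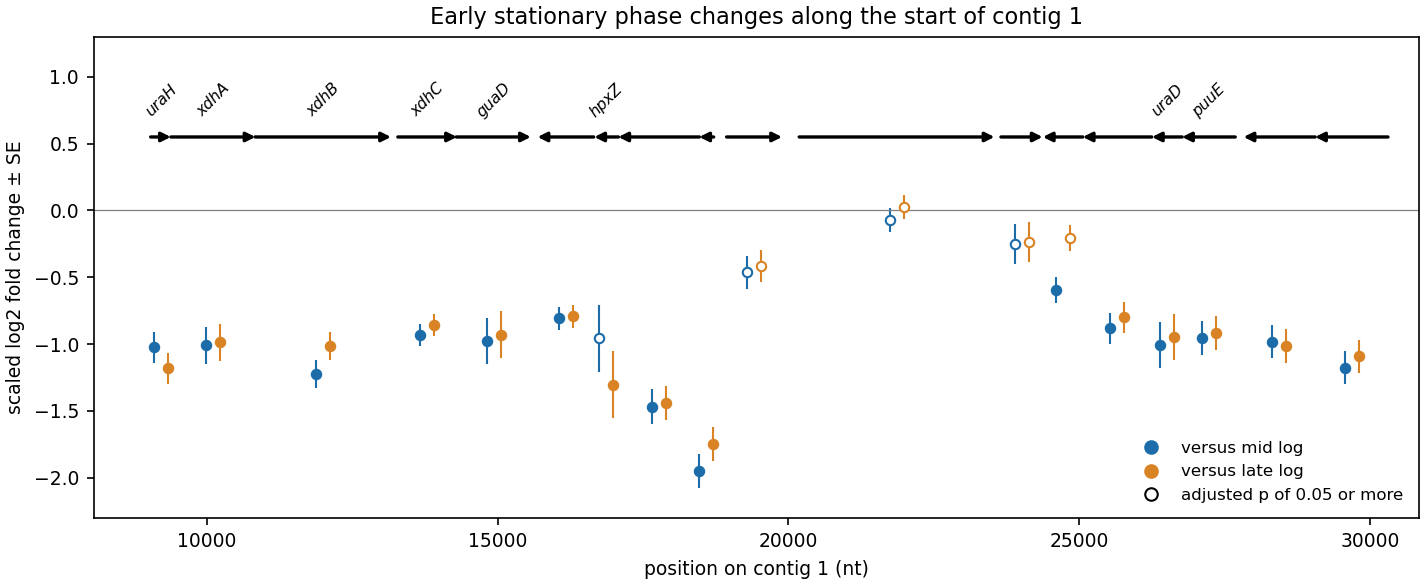
Scaled log2 fold change ± SE of early stationary against mid log and late log for 18 tested features along contig 1 from position 9038 to 30303, with arrows for gene strand. Filled points passed the limma test; 14 lie below 0 and pass in each comparison.

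Named rises by the rule were rnk (0.39 scaled), tssE (0.30), fabB (0.25), lpxC (0.24), rplS (0.24), spdR (0.23), secE (0.23), ybeY (0.22), ybgF (0.24), cyoE (0.22), msrB (0.22) and tatB (0.23), drawn from 180 eligible symbols with unscaled changes of 0.59 to 0.75. rnk encodes a regulator of nucleoside diphosphate kinase, tssE a part of the type VI secretion baseplate and fabB a fatty acid synthase. None passed after scaling (limma, adjusted p of 0.129 for fabB to 0.57 for secE). Unscaled, 1939 features passed, 1914 higher and 25 lower. After scaling 97 passed, 40 higher and 57 lower, and 63 of the 97 were among the unscaled calls. Of the 25 unscaled falls, 14 lay in the contig 1 stretch. Voom called 1552. The unscaled count was 496 without mid log replicate 1, 1116 without mid log replicate 2, 1237 without early stationary replicate 1 and 1189 without early stationary replicate 2. The scaled count was 45 (20 higher, 25 lower), 62 (31 and 31) and 42 (20 and 22) without mid log replicate 1, 2 and 3 and 57 (22 and 35) without early stationary replicate 2. Without early stationary replicate 1 it was 84, with 47 higher and 37 lower.

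Early stationary was compared with late log to find what changes at the end of growth. uraH fell from 44.1 ± 8.98 to 20.4 ± 3.02 TPM (scaled -1.18 ± 0.12, limma adjusted p = 0.000685) and ASC70_RS00090 from 27.0 ± 1.25 to 7.96 ± 1.00 TPM (-1.75 ± 0.13, 0.000121). ASC70_RS10020 rose by 1.64 ± 0.22 from 19.6 ± 8.67 TPM and ASC70_RS24095 by 1.31 ± 0.14 from 80.9 ± 14.6 TPM (n = 3), again the 1st and 3rd of such locus tags, with the next feature on contig 6 between them at 1.41. No gene with a symbol met the rule for rises. putA rose by 0.72 ± 0.13 and gltB by 0.64 ± 0.11, both chosen after their values were seen. Unscaled, 39 features passed, 25 higher and 14 lower, and after scaling 38 passed, 18 higher and 20 lower, with 31 shared. Voom called 45. The unscaled split was 13 higher and 14 lower without late log replicate 1, 41 and 8 without replicate 2, and 13 and 9, 22 in all, without replicate 3. The scaled count was 25, with 10 higher and 15 lower, without late log replicate 1 or replicate 3, and 11 were higher and 16 lower without early stationary replicate 2. Over the 3 phases 983 features differed unscaled and 68 after scaling (limma F test). The unscaled count was 137 without mid log replicate 1, 232 without mid log replicate 2 and 608 without early stationary replicate 2. The scaled count was 38, 40 and 37 without mid log replicate 1, 2 and 3 and 29 without early stationary replicate 2.

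Gene lists were compared to see whether whole pathways moved with growth phase. Ribosomal proteins lay below the shift of all features: of 51 members 46 were below 0 in early stationary against mid log on the scaled values, with a median of -0.16. rpsD (-0.40 ± 0.06) and rplT (-0.32 ± 0.07), chosen after their values were seen, fell on that scale and did not pass without scaling (unscaled changes -0.02 and 0.06). In the unscaled fit 10 ribosomal protein genes rose and 0 fell. Adjusted over the list alone, 2 rose and 0 fell unscaled, and 18 fell after scaling. With camera's preset correlation, 0 of 17 lists were called in each comparison unscaled (0, 1 and 0 with unadjusted p under 0.05 for late log against mid log, early stationary against mid log and early stationary against late log). After scaling, 6 lists were lower in late log than mid log and 5 in early stationary than mid log, among them ribosomal proteins (adjusted p = 3.91e-05 and 1.73e-10), translation factors (0.0194 and 0.00358), amino acid biosynthesis (0.0194 and 0.00358) and the TCA cycle (0.0194 and 0.00506), and ribosomal proteins alone were lower in early stationary than late log (0.00364). With an estimated correlation 0 lists passed (lowest adjusted p = 0.209 in late log against mid log and 0.0897 and 0.714 in early stationary against mid log and late log). At the preset correlation, chaperones and aminoacyl-tRNA synthetases were lower in late log only (0.0194 and 0.0452) and cell cycle regulators in early stationary only (0.0203); whether the phases differ in this was not tested. With fry, which tests a list by itself and so follows the shift, 0, 16 and 0 of 17 lists passed unscaled and 3, 6 and 0 after scaling.

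In the other lists of at least 5 members, members that rose unscaled in early stationary against mid log numbered 11 of 14 for DNA replication, 10 of 18 for cell division, 10 of 49 for amino acid biosynthesis, 9 of 19 for the flagellum, 6 of 16 for SOS and DNA repair, 6 of 8 for ATP-dependent proteases, 5 of 13 for aminoacyl-tRNA synthetases, 5 of 8 for chaperones, 4 of 12 for oxidative stress, 3 of 8 for complex I and 3 of 8 for RNA polymerase. 3 of 5 rose for nitrogen assimilation, 2 of 9 for phosphate starvation, 2 of 11 for translation factors, 2 of 7 for cell cycle regulators and 1 of 9 for the TCA cycle, and 0 fell in any of these lists. Over all tested features 1914 of 4609 rose in that fit, so these counts carry the common shift. After scaling, the members that passed were gltB, which rose, and the cell cycle regulator chpT, chosen after its value was seen. On the scaled values chpT fell by 0.48 (SE 0.11), and it did not pass unscaled (-0.16).

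The E. coli libraries had no control group, so levels are given without a comparison. From the plasmid bilA measured 10.3 ± 1.95 TPM, bilB 2.47 ± 0.68, bilC 3.87 ± 1.37 and bilD 5.68 ± 0.31 (SD, n = 3), on 230 to 275, 51 to 70, 67 to 120 and 366 to 425 reads per library. tetR, the repressor of the inducible promoter on the same plasmid, was at 257 ± 18.3 TPM, 25.2 ± 3.23 times bilA. The kanamycin resistance gene kanR, chosen after its value was seen, was at 946 ± 108 TPM, 93.6 ± 20.6 times bilA. aphA and rep of the plasmid list lie on the chromosome here, at 53.5 ± 5.67 and 7.60 ± 1.02 TPM. The highest protein-coding gene was lpp, the outer membrane lipoprotein, at 46130 ± 4075 TPM, followed by yobF at 11246 ± 977, rpsU at 10478 ± 737, cspA (cold shock protein) at 9287 ± 817, rpmH at 8950 ± 225, acpP (acyl carrier protein) at 8702 ± 835, cspE at 7297 ± 508 and rpsT at 6362 ± 597. rpmE, infA, secG, rplU, csrA, ivbL and rpmB completed the first 15, between 2307 and 3396 TPM. rRNA took 34.8% ± 2.00 of TPM, tRNA genes 22.9% ± 0.26, small non-coding RNAs 7.74% ± 0.79 and ribosomal protein genes 5.80% ± 0.41. Protein-coding features together took 27.8% ± 1.74.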

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

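The tests on the rise of nearly all features, on the block's unscaled fall and on the splits of libraries were chosen after the results had been seen. The other tests were chosen before their own outcomes were seen, but for patterns that had already been found in these data. The early stationary table leaves out 170 features that the other tables list, and 60 of these had at least 3 reads in each of the 6 mid log and late log libraries. This signal lies in data that the comparisons do not use. The most any of them had was 51 reads over the mid log libraries and 48 over the late log libraries, and they were left out of every comparison. Their summed TPM was 85.9 to 91.2 in mid log, 98.5 to 114 in late log and, as the part of the total not listed, 94.6 to 104 in early stationary, all unscaled. Listed features had at least 30 reads summed over the early stationary libraries, so the omission may depend on the early stationary value. Low features that fell could then be missing from the counts of falls. Whether single ones fell was not tested.

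The 1st pattern is that nearly all features called between early stationary and mid log rose. Since TPM of all features share 1 total, a lower share of a few abundant RNAs raises the rest. After median-of-ratios scaling 41.2% of the calls were rises, but the scaling centres the median feature, so this share cannot tell whether that was the cause. Short features argue against a more complete rRNA depletion in early stationary as the whole cause. The 65 features under 100 nt, which are not rRNA, had a median scaled change of -0.31 (quartiles -0.51 and -0.14). Their median was also -0.31 in late log against mid log, where the shift of all features was smaller. Longer stable RNAs were mixed in early stationary against mid log: ssrA was at -0.40, ssrS at -0.41, ffs at -0.13 and rnpB at 0.10 (scaled, none passing in limma). Lower levels of abundant stable RNA relative to the median feature, whether in the cells or in the preparation, stay open, and scaled and unscaled changes cannot both be read as amounts per cell.

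The 2nd pattern is the fall of the genes from uraH to the end of the block on contig 1. The shared total is not the source, since the block's median change without scaling was -0.64. No single library carried it, since the median scaled change nearest to 0 with a library left out was -0.85. Neighbouring genes on 1 strand under 50 nt apart changed together across the genome more than neighbours on opposite strands (r 0.48 against 0.10, difference 0.385 over 1382 and 1607 pairs, the block's own included). This may account for runs of like change on 1 strand but not for their direction. The falling genes of the block lie on both strands, so such pairs cannot join the whole block. Regulation of these genes with growth phase is a hypothesis that stays open and was not tested otherwise.

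The 3rd pattern is that bilD took a larger share of the Bil transcripts in E. coli than in Caulobacter. The lengths used as divisors are too alike to account for it. With Caulobacter lengths in E. coli the difference, E. coli minus Caulobacter, was 15.2 percentage points, against 14.0 as annotated. That swap kept the reads of the plasmid genes, so it tests the divisor only. With overlaps taken off the lengths it was 13.8 points. That test left the reads unchanged, so reads lost or shared at gene junctions cannot be excluded. The annotated Bil genes themselves differ in length and in their overlaps between plasmid and Caulobacter, so their sequences are not the same. The gene sequences, the organism, the inducible promoter and the plasmid copy differ at once, so what remains open cannot be divided among these.

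For the comparisons of 3 against 3 libraries, 10 splits are too few for a share under 0.05. Unscaled, late log against mid log gave 118 features and the highest other split 0; early stationary against mid log 1939 and 0; early stationary against late log 39 and 1. After scaling these were 0 and 0, 97 and 3, and 38 and 1. The lists called were 0 against 1, 0 against 0 and 0 against 3. Over the 3 phases the real grouping was the only 1 of 100 splits to give as many features, with 983 against 278 unscaled and 68 against 40 scaled. This argues against a chance division of the libraries there but does not exclude it, since only a sample of the possible splits was drawn.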

How the results depend on the processing

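Of 352 values from alternatives to results that answer a comparison, 280 were alike, 49 weaker, 16 stronger, 5 moved and 2 reversed. A count was alike when its total changed by at most 1.5 times, whatever its split, a test when it kept its direction and side of the threshold, and a level when it stayed within its SD. For named genes, 953 of 1199 were alike, 212 weaker, 1 stronger, 19 moved and 14 reversed. Settings on scaled values, voom, and any-phase settings other than the block, the pseudocount of 0.1 and coding rescaling were chosen after seeing the data, as were the lists with a library left out. A count-model test was planned for the case of deposited raw counts and was not run, since TPM was deposited. The recovered reads were tested with voom only. The cause was not tested where a value changed, unless stated.

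Scaling lowered the counts of the comparisons with mid log and over any phase, but early stationary against late log gave 36, 38 and 37 features against 39, of which 30, 31 and 31 were shared, with 18 higher in each and 18, 20 and 19 lower against 25 higher and 14 lower. Late log against mid log fell from 118 features to 0 with coding features rescaled, with median-of-ratios scaling or with quantile normalization; early stationary against mid log from 1939 to 75, 97 and 78 (37, 40 and 39 higher; 38, 57 and 39 lower); any phase from 983 to 64, 68 and 62. Lists called rose from 0 to 6, 5 and 1 in the order late log against mid log, early stationary against mid log and early stationary against late log, under coding rescaling and under median-of-ratios scaling. With median-of-ratios scaling and the correlation estimated per list, 0 lists passed in each comparison. Late log against mid log gave 63 with a pseudocount of 5, 184 with TPM of at least 10 and 471 with only the phases compared (5 scaled). A log2 change of at least 1 left 8, 30 and 11, by construction.

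Whether replicate numbers pair the libraries cannot be told from so few libraries. Same-number residuals correlated at -0.17 to 0.14, 2 of 9 pairs above 0.1, and different numbers at -0.16 to 0.13. Between mid log and late log, the same-number pairs (0.141, 0.070 and 0.074) lay above every different-number pair (highest 0.013). Pairs with early stationary showed no such order. With the replicate block, 95, 2035 and 39 features were called, and 1121 in any phase. Scaled lists were then 5, 5 and 1, with aminoacyl-tRNA synthetases no longer called in late log against mid log. The block gave bilC an adjusted p of 0.0347 across phases, and changed no other Bil call.

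With 1 library left out, counts ranged from 1 to 437 in late log against mid log (scaled 0 to 7), 496 to 2310 in early stationary against mid log (42 to 111), 22 to 51 in early stationary against late log (25 to 44) and 137 to 1369 in any phase (29 to 68). Unscaled lists, run without mid log replicate 1, late log replicate 2 or early stationary replicate 3 only, stayed at 0, and the scaled lists were not run with a library left out. Adjusted p across phases ranged from 0.00893 to 0.0357 for bilA, 0.0759 to 0.339 for bilB, 0.0714 to 0.339 for bilC, 0.00893 to 0.0893 for bilD and 0.0179 to 0.0714 for the sum. Share differences, Caulobacter minus E. coli, ranged from -6.14 to -2.79 points for bilC. bilB in early stationary against late log ranged from -0.0716 to 0.18, with -0.00255 without late log replicate 1.

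Across phases, the exact permutation test gave bilA an adjusted p = 0.746 with coding rescaling and 0.835 with median-of-ratios scaling, bilD 0.754 and 0.921 (reversed), and the sum 0.746 and 0.835. The bilC share difference reversed to 0.22 as a ratio to the median Bil gene. Coding-rescaled, median-of-ratios and quantile values reversed bilA (-0.0330, -0.0180, -0.0368) and bilD (-0.0437, -0.0243, -0.0370) in late log against mid log and bilB (-0.0158, -0.0299, -0.0450) in early stationary against late log. bilD in early stationary against mid log reversed to -0.00156 and -0.0241 with the last 2, and bilC in early stationary against late log to -0.00688 with quantile normalization. In E. coli, coding rescaling moved bilA to 37.0, bilB to 8.79, bilC to 13.8 and bilD to 20.4 TPM by its smaller total. Ranked among all features, bilD moved to percentile 46.8.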

Other observations

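The tests below were chosen after the results had been seen. A run of 6 adjacent features on the minus strand of contig 12, from 147713 to 155114, rose in early stationary against mid log by 0.81 to 1.42 on the scaled log2 scale, with ASC70_RS24095 at its end, and all 6 also rose unscaled. Another run of 3 features on contig 6, from 608618 to 612823, fell on the scaled values only, at -0.57 to -0.43, and none of the 3 passed unscaled. Features called after scaling had called neighbours of the same direction more often than when the calls were placed at random over the features. There were 21 adjacent pairs against a mean of 1.03 in 10000 permutations (permutation p = 0.0001, the smallest they can give). Without the contig 1 block there were 10 against 0.74. The permutations treat neighbours as independent, but close neighbours on 1 strand changed together (r 0.48), which may be signal or noise. The p-value therefore does not show that phase changes cluster beyond this.

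Among stable RNAs, ssrA (tmRNA) stood at 13.8% ± 0.74 of TPM in mid log, 15.02% ± 0.10 in late log and 13.6% ± 1.08 in early stationary (SD, n = 3), and ssrS (6S RNA) at 4.87% ± 0.41, 4.73% ± 0.29 and 4.75% ± 0.10. rnpB (RNase P RNA) was at 0.160% ± 0.02, 0.190% ± 0.04 and 0.223% ± 0.02, and ffs (signal recognition particle RNA) at 0.538% ± 0.05, 0.544% ± 0.05 and 0.638% ± 0.03. None of the 4 passed in early stationary against mid log after scaling (limma, lowest adjusted p = 0.282).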
